A study of Homo sapiens with 6 samples.

How the data were processed

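Total RNA of HCT116 cells was labelled with biotin and hybridised to Affymetrix human expression arrays, 3 from cells with the NFX1-91 hairpin and 3 from cells with the β-galactosidase hairpin, per the labels' protocols. Groups and replicate numbers come from the labels. The deposited table holds intensity values on a linear scale for 22215 probe sets. Each column sums to 1, so a deposited intensity is a share of its array's total. How the authors summarised and scaled the probes is not given in the sources used here, and the scale's origin is read from the values alone. Each array also holds 397 to 451 values that repeat 1 low value, which looks like a lower limit and cannot order dim probe sets. Scanner files were not used here. The table has no rows for the Affymetrix control probe sets, so the planned ratio of 3′ to 5′ signal was not analysed here.

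The design had set an offset of 16 for linear values, which has no meaning on shares. Each array was therefore multiplied to a mean of 500, a value chosen after the values were seen, and log2(signal + 16) was taken. That is one factor for all arrays and changes no ratio without the offset. No further normalization was applied. Between 24.1% and 25.9% of the probe sets of an array lay below the offset.

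Probe sets were named through the platform annotation given with the series: 19064 had 1 gene, 1043 several and 2108 none listed. Symbols were checked by gene identifier against a table of RefSeq genes on GRCh38.p14, used only for names and genomic lengths; 19052 matched, 12 did not, and 0 symbols changed. No coordinates are given, since the files name no build. A gene was represented by the brightest of its single-gene probe sets over all 6 arrays, which left 11963 genes.

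Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a variance trend, unpaired, two-sided), with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Before the data were examined, 30 gene lists were fixed, and 29 were tested with limma's camera at an inter-gene correlation of 0.01, adjusted over the lists. Beside it stand camera with an estimated correlation, by which 0 lists passed, and fry. With an estimated correlation camera also takes its degrees of freedom from the few arrays and not from the genes. A list can hardly pass that way, so a lost call decides little. By fry, which does not compare a list with other genes, 12 of 29 lists moved on balance in a single direction and 25 changed in either direction, so it does not single out the lists called by camera. NFX1 probe sets also had an exact permutation test.

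The rule for named genes was also fixed before the data were examined. It took NFX1, TERT and NFKB1; the 12 largest rises and 12 largest falls among genes past the threshold, with groups that did not overlap and a brighter group mean above the median of all genes; up to 4 members per list with the smallest adjusted p; and ACTB and GAPDH. It gave 140 genes.

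The steps were tested on simulated data made from the real genes' means and spreads. In 10 simulated sets of 200 changed genes each, 25% of 1.25-fold changes were recovered, 55.2% of 1.5-fold, 83.8% of 2-fold and 98.4% of 4-fold, and 3.67% of calls were false. A shifted list was recovered in 20 of 20 sets, and 1 of 20 sets without a shift gave a call. The real comparison called 3890 genes, far more than 200. The adjusted threshold was therefore stricter in the simulation, and its recovery rates may understate those of the real comparison. Genes were simulated as independent, so the rate of false list calls among correlated genes was not tested.

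Alternatives were quantile normalization, median centring, leaving out genes below the 40th percentile of brightness, offsets of 1 and 64, no variance trend, a robust prior, the mean of a gene's probe sets, leaving out shared (_s_at and _x_at) probe sets where the gene has another kind, array weights, a replicate block, leaving out each array, a fold of 1.5, a threshold of 0.01, and camera on ranks. An alternative without any offset was chosen after the data were seen.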

Results

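HCT116 is an established human colon cancer cell line. Cells carrying a lentiviral hairpin against NFX1-91 were compared with cells carrying a control hairpin against β-galactosidase, with 3 arrays in each group. NFX1-91 is a splice form of NFX1, a zinc finger protein known as a repressor of the TERT promoter. NFKB1 is another published target. The arrays measured 22215 probe sets, from which 11963 genes with a probe set of their own were tested. Nothing in the labels says whether the 3 arrays of a group came from separate cultures, so the p-values measure the spread between these arrays, which may be technical. The number of arrays limits the precision. Pearson correlation between arrays ran from 0.992 to 0.995 within groups and from 0.983 to 0.985 between groups.

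The comparison asked which transcripts differed in cells expressing the NFX1-91 hairpin. HMGA2, a chromatin protein of embryonic tissues, rose most among the genes that met the naming rule, from a scaled signal of 892 ± 11.2 to 5061 ± 261 (SD, n = 3 per group). DPYSL2, a microtubule-binding protein, fell most, from 503 ± 47.8 to 51.8 ± 9.80. NFKB1, which encodes the p105 and p50 subunit of NF-kB, fell 2.35-fold. Of 22 measured S phase genes 11 were lower and 1 higher, of 23 unfolded protein and integrated stress response genes 14 and 3, and of 20 p53 targets 3 and 10. The calls of these 3 lists did not hold with an estimated correlation (camera adjusted p = 0.310, 0.664 and 0.664). The estimates were -0.021, 0.131 and 0.127. For S phase genes the estimate lay below the fixed 0.01, so correlation does not account for the lost call. Their unadjusted camera p went from 4.04e-05 to 0.0107, as that setting has far fewer degrees of freedom. The lost calls therefore do not decide whether the lists moved. Over all genes 1760 were higher and 2130 lower at an adjusted p under 0.05, and 62 and 156 of them changed at least 2-fold. The 3 arrays of each group did not overlap for 5199 genes, or 43.5%, against 10% by chance. Folds are on the log2(signal + 16) scale, which understates the change of dim genes.

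The hairpin's own target was read by 3 NFX1 probe sets, and each may detect NFX1-91, its sister form NFX1-123 or both. The brightest of them had a signal of 148 ± 10.7 in control arrays and 134 ± 8.39 in NFX1-91 shRNA arrays. Its log2 fold change was -0.13 (SE 0.095, adjusted p = 0.362). For the middle one, a shared probe set, the log2 fold change was -0.06 (SE 0.122, adjusted p = 0.775 over probe sets). The dimmest fell from 19.6 ± 4.17 to 7.42 ± 2.48, a log2 fold change of -0.60 (SE 0.143, adjusted p = 0.0137 over probe sets), and lay at percentile 21.7 of brightness. With an offset of 1 in place of 16 its log2 fold change was -1.32. From the brightest to the dimmest, the exact two-sided permutation p was 0.2, 0.5 and 0.1, and 0.1 is the smallest that 3 against 3 arrays allow. The dimmest NFX1 probe set thus passed the limma threshold and the other two did not.

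**Figure D1:**
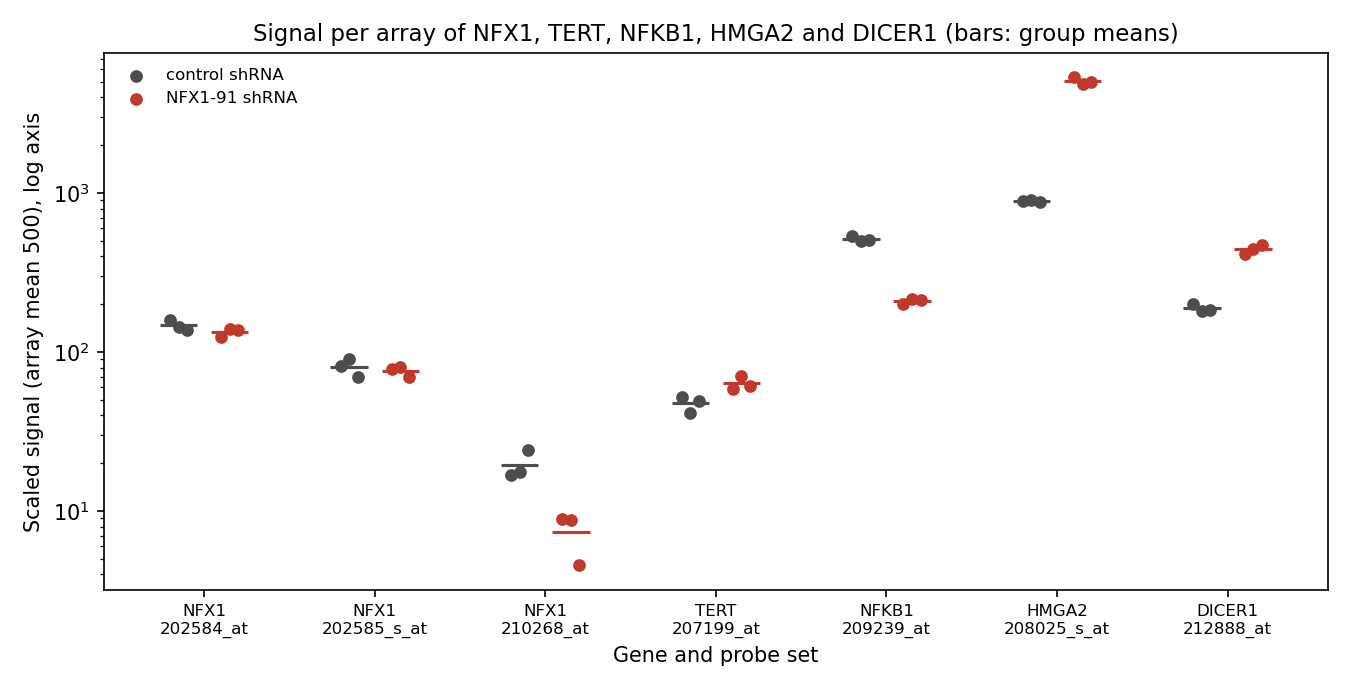
Scaled signal on a log axis for 7 probe sets of 5 genes, with 1 point per array (n = 3 per group) and bars at the group means. NFKB1 went from 514 to 210 and HMGA2 from 892 to 5061, while the groups of the brightest and of the middle NFX1 probe set overlapped.

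Of the published targets of NFX1-91, TERT, the catalytic subunit of telomerase, had a log2 fold change of 0.32 (SE 0.124, adjusted p = 0.0743), with signals of 47.6 ± 5.38 and 63.5 ± 5.98. It passed the threshold when dim genes were left out (adjusted p = 0.0428) or without a variance trend (0.0413), and over all alternatives its adjusted p ran from 0.0413 to 0.231. NFKB1 fell from 514 ± 21.6 to 210 ± 8.90 (log2 fold change -1.23, SE 0.068, adjusted p = 1.76e-06). Adjusted over the list alone, 1 of the 3 genes was higher (TERT) and 1 lower (NFKB1). Among 6 measured relatives and partners of NFX1, 2 were higher and 1 lower over all genes, and 3 and 1 adjusted over the list alone. MYC, a transcription factor of cell growth, rose by 0.35, and USF2, a factor that binds E-boxes, fell by 0.66.

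Other large rises were those of NUP58, a nuclear pore protein (log2 fold change 1.90), PLEKHB2 (1.76), CEMIP2 (1.76), the collagen COL13A1 (1.69), the peroxidase PXDN (1.44), AMMECR1 (1.43) and tissue factor F3 (1.38). The list went on with the actin-binding LIMA1 (1.37), EOGT (1.37), the NKG2D ligand ULBP2 (1.36) and the non-coding DLEU2 (1.28). Large falls included the splicing regulator RBM10 (-2.15), the oligosaccharyltransferase subunit STT3A (-2.07), the mitotic phosphatase CDC25B (-2.01), the leucine transporter SLC7A5 (-1.90) and spermidine synthase SRM (-1.90). Further falls were those of COQ6 (-1.89), GALNT12 (-1.82), CCDC85C (-1.82), the DNA repair scaffold XRCC1 (-1.81), RAB26 (-1.81) and the nucleoside transporter SLC29A1 (-1.72). For all of these 24 genes, HMGA2 and DPYSL2 included, the direction and the call held in 360 of 360 values from 15 alternative settings, with a highest adjusted p of 0.00157. The choice of probe set was barely tested for them, since 17 have a single probe set and the 11 read by a shared probe set have no other kind. The 7 with several probe sets kept call and direction by the mean. For COL13A1 and DLEU2, however, no other probe set was called the same way by itself.

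**Figure D2:**
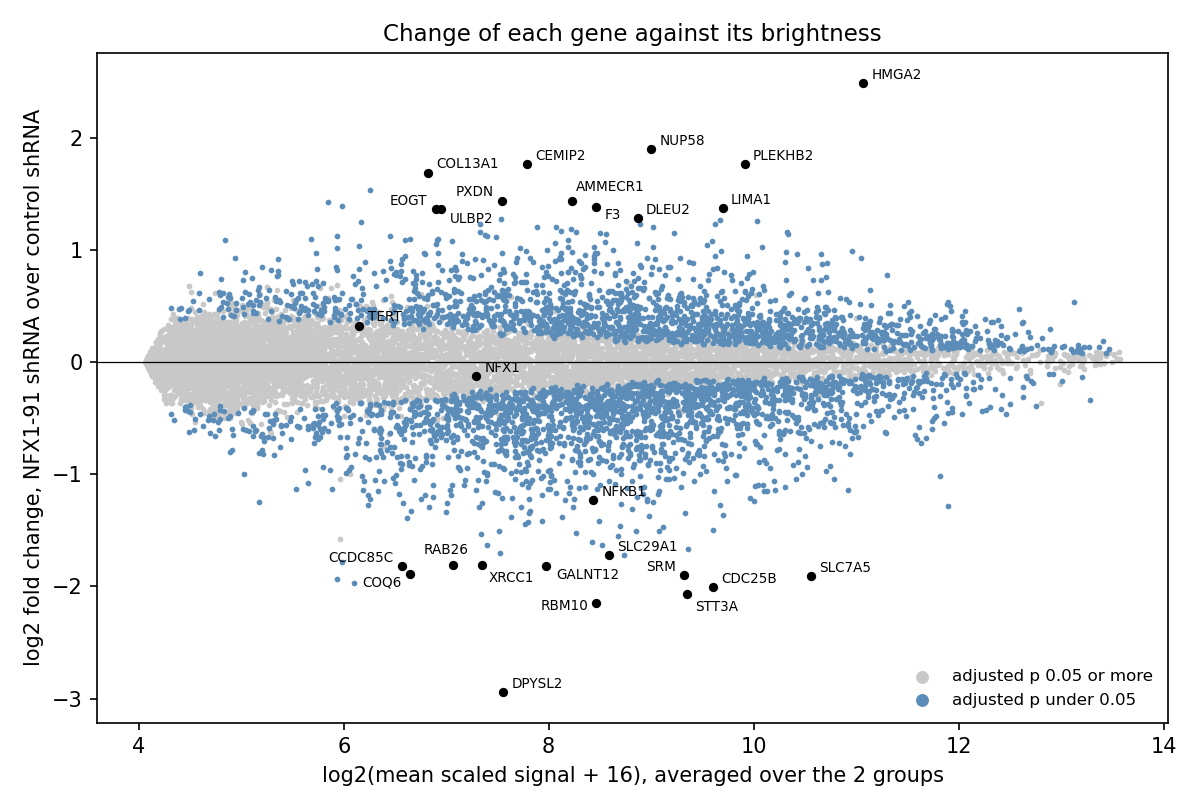
log2 fold change of 11963 genes against brightness, both on the log2(signal + 16) scale, with genes past an adjusted p of 0.05 in blue. Black points mark the 24 genes with the largest rises and falls, NFX1, TERT and NFKB1, and HMGA2 (2.48) and DPYSL2 (-2.94) are the extremes among them.

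Among the 22 S phase genes, which act in DNA replication, 11 fell, 1 rose and 10 did not pass, and adjusted over the list alone 12 fell and 1 rose. MCM4, a subunit of the replicative helicase, fell by 0.83, the licensing factor CDT1 by 0.81, GINS2 by 0.63 and thymidylate synthase TYMS by 0.29, while the riser was the sliding clamp PCNA (0.11). The list was lower than other genes by camera (adjusted p = 0.00117), and had an adjusted p = 0.310 with an estimated correlation. G2 and mitosis genes went both ways, with 5 higher and 8 lower of 25, and 7 and 8 adjusted over the list alone (camera adjusted p = 0.985). The Aurora kinases AURKB (-0.94) and AURKA (-0.55) and the motor protein KIF11 (-0.89) fell, and the spindle factor TPX2 rose by 0.43. AURKA did not pass with shared probe sets left out (-0.33, adjusted p = 0.295).

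Among 23 measured genes of the unfolded protein and integrated stress responses 14 fell, 3 rose and 6 did not pass, with 14 and 3 adjusted over the list alone. The pseudokinase TRIB3 fell by 1.17, asparagine synthetase ASNS by 0.78, the glutathione-degrading CHAC1 by 1.39 and the mTORC1 inhibitor DDIT4 by 0.59. The 3 that rose, DNAJB9 (0.51), HYOU1 (0.42) and HSPA5 (0.21), encode chaperones of the endoplasmic reticulum. Camera placed the list below other genes (adjusted p = 0.00223), with an adjusted p = 0.664 with an estimated correlation. Of 20 measured p53 targets 10 rose and 3 fell, and 12 and 3 adjusted over the list alone. The kinase PLK2 rose by 0.61, TIGAR by 0.80, the cell cycle inhibitor CDKN1A by 0.52 and the death receptor FAS by 0.84. Those that fell were the cytokine GDF15 (-0.57), the pore-forming BAX (-0.77) and GADD45A (-0.34). The list was higher by camera (adjusted p = 0.0208), which became 0.0629 on ranks and an adjusted p = 0.664 with an estimated correlation. Members that moved against their list were named after their values were seen.

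**Figure D3:**
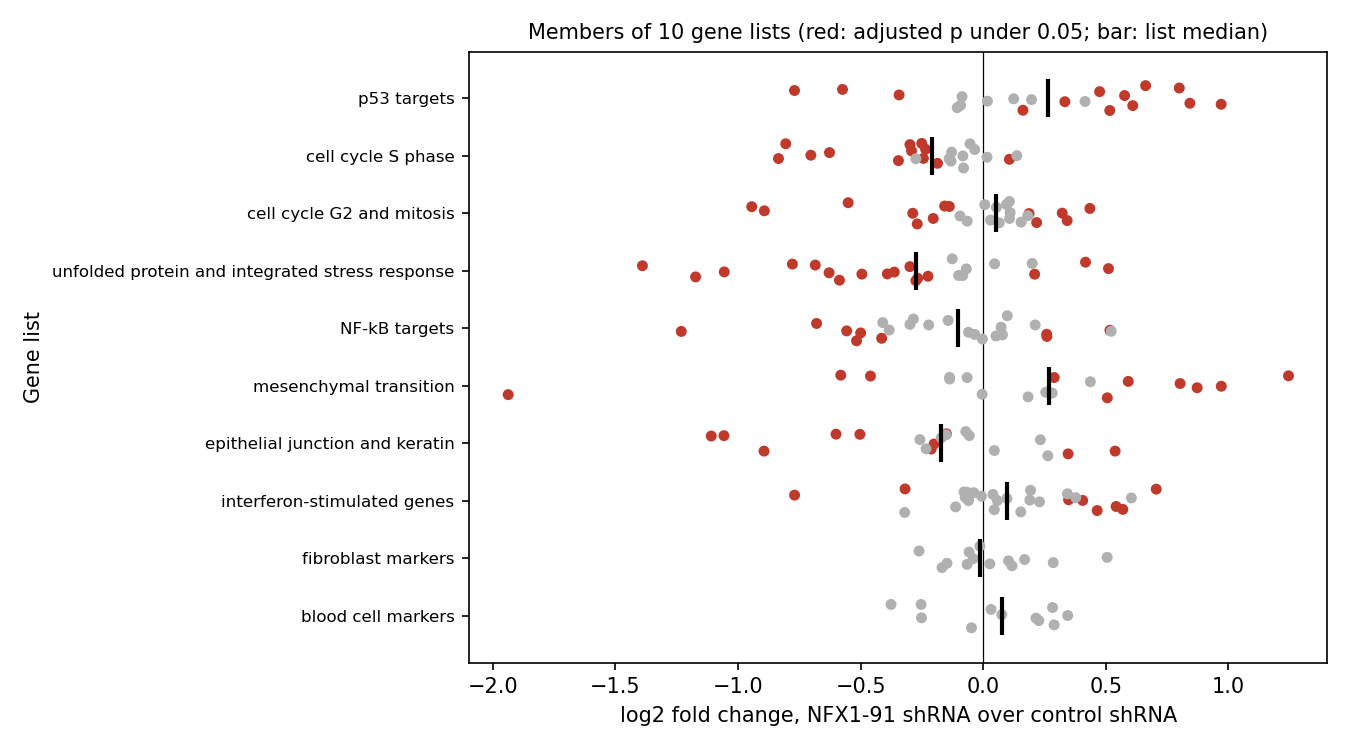
log2 fold change of each measured member of 10 gene lists, 1 point per gene, red where the adjusted p over all genes was under 0.05 and grey otherwise, with a bar at the list median. The median was -0.21 for S phase genes, -0.27 for the stress response genes and 0.26 for p53 targets, and no fibroblast or blood cell marker passed.

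No other list passed the main camera test. Of 24 NF-kB targets 3 rose and 6 fell (adjusted p = 0.466), the same counts as over the list alone. NFKB1 itself, the inhibitor NFKBIA (-0.50) and TNFAIP2 (-0.68) were among those that fell, and IER3 rose by 0.26. In the hypoxia and glycolysis list 8 of 19 rose and 2 fell, with 9 and 2 over the list alone (adjusted p = 0.098, and 0.0404 on ranks). The glycolytic regulator PFKFB3 rose by 1.03, whereas triose phosphate isomerase TPI1 fell by 1.28, and its 3 probe sets all fell. Epithelial junction and keratin genes had 2 higher and 8 lower of 19, unchanged over the list alone (adjusted p = 0.131). Claudin CLDN7 (-1.11) and the epithelial regulators GRHL2 (-1.06) and ESRP1 (-0.89) fell, and the keratin KRT18 rose by 0.54. Of 18 mesenchymal genes 7 were higher and 3 lower, and 9 and 3 over the list alone (adjusted p = 0.294). CCN2 rose by 1.24 and the repressor ZEB1 by 0.87, and the actin-binding TAGLN fell by 1.94. THBS1 rose by 0.97, with a log2 fold change of -0.26 (adjusted p = 0.184) with shared probe sets left out.

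Immediate early genes split into 7 higher and 6 lower of 21, and 8 and 6 adjusted over the list alone (adjusted p = 0.781), with JUND (-1.05), EGR1 (-1.12) and FOSL1 (-0.96) lower and the signal of KLF10 down from 1989 to 988. Of 11 Wnt targets 4 rose and 1 fell (adjusted p = 0.131), SOX9 by 0.63 and CCND1 by 0.34, while the Wnt inhibitor DKK1 fell by 0.60. The counts were the same over the list alone, as they were for 27 interferon-stimulated genes with 6 higher and 2 lower (adjusted p = 0.300). IRF7 (0.71), ISG15 (0.35) and IRF9 (0.54) were higher and IFI35 (-0.77) lower. In the RNA interference machinery 3 of 8 rose and 0 fell, and 3 and 1 over the list alone (adjusted p = 0.434). The small RNA processing enzyme DICER1 rose by 1.16, AGO1 by 0.62 and TARBP2 by 0.28. Histone genes had 3 higher and 1 lower of 9 by both adjustments (adjusted p = 0.355), with H2BC9 (1.01) and H2BC12 (0.96) higher and H2AX (-0.50) lower.

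MYC targets had 7 higher and 5 lower of 20, and 8 and 5 over the list alone (adjusted p = 0.849), with SRM, PA2G4 (-0.54) and CDK4 (-0.35) lower. Oxidative phosphorylation genes had 6 higher and 6 lower of 22, and 10 and 6 over the list alone (adjusted p = 0.802), CYC1 falling by 0.68 and NDUFS1 rising by 0.41. Cholesterol synthesis genes had 4 higher and 3 lower of 13, and 4 and 4 over the list alone (adjusted p = 0.835), INSIG1 falling by 1.22. In lipid synthesis 1 of 8 rose and 3 fell, among them FASN (-0.89), by both adjustments (adjusted p = 0.513). Oxidative stress genes had 5 higher and 4 lower of 17 by both adjustments (adjusted p = 0.925), NQO1 falling by 0.49. For the apoptosis list 2 of 18 were higher and 2 lower by both adjustments (adjusted p = 0.781), BAK1 rising by 0.36. Heat shock genes had 2 higher and 1 lower of 12, and 2 and 0 over the list alone (adjusted p = 0.913), and DNAJA1 (0.36) read -0.25 with shared probe sets left out. Ribosomal protein genes had 2 higher and 1 lower of 19, and 1 and 1 over the list alone (adjusted p = 0.513), RPLP1 falling by 0.34. MHC class I genes had 0 higher and 2 lower of 12 by both adjustments (adjusted p = 0.466), TAPBP (-0.59) and HLA-E (-0.32), the latter 0.03 with shared probe sets left out. Of 10 MHC class II genes 0 passed by either adjustment (adjusted p = 0.781). Camera for the relatives and partners of NFX1 gave an adjusted p = 0.466. Median, mean and test differed in sign for G2 and mitosis, MYC, cholesterol, oxidative phosphorylation, oxidative stress and heat shock genes and for fibroblast markers.

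No list of markers of other cell types passed. By limma, 0 of 13 fibroblast markers (adjusted p = 0.868), 0 of 11 blood cell markers (0.806) and 0 of 8 embryonic kidney cell markers (0.913) passed, by either adjustment. In the keratinocyte list 2 of 9 rose and 1 fell by both adjustments (adjusted p = 0.513), SFN (0.32) and LAMB3 (0.44) being higher and KRT10 (-0.19) lower. In the colon differentiation list CA2 rose by 0.44 and 21 of 22 did not pass, by both adjustments (adjusted p = 0.631). The housekeeping gene ACTB rose by 0.19 (SE 0.030, adjusted p = 0.000812), and GAPDH had a log2 fold change of 0.08 (SE 0.030, adjusted p = 0.0637).

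All calls are from limma with Benjamini-Hochberg adjustment. The excess of lower over higher calls was lost with centring of each array on its median, which gave 1956 higher and 1874 lower. In that setting 110 of the 111 named genes called kept call and direction, and 0 reversed. Of 1628 called genes with other probe sets, 820 had another called the same way and 49 one called the opposite way.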

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

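Tests chosen after the result was seen were both comparisons of the NFX1 probe sets with each other, the microRNA families taken singly, and the brightness and labelling tests of gene length; the others below were written before their values were computed, though after the largest changes had been seen.

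Outside the tested genes, probe sets annotated to several genes or to none also differed between the groups: 278 were higher and 304 lower in NFX1-91 shRNA arrays. They were picked out because the comparison of genes did not use them. The real grouping of the 6 arrays gave 3890 changed genes and the highest of the other splits gave 0. The real grouping was 1 of 10 splits, too few for a share under 0.05. Each other split mixed arrays of both groups, so any difference between the groups widened its spread. The 0 therefore does not decide whether the changes arose by chance.

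Of the NFX1 probe sets the dimmest fell past the threshold and the others did not pass, which does not show that they differ. On the planned scale the bounds of 2 SE around the change of the brightest, -0.13, and around the fall of the dimmest overlapped. Such an overlap is not a test of the difference, and no such test was run. An offset of 1 was tried after that overlap was seen, with the values at that offset already known. The brightest then read -0.14 (SE 0.106) against -1.32 (SE 0.349), and the bounds of the falls (0.355 and 0.626) did not overlap. That decides nothing, as the dim signals lie around or below the offset of 16. Noise stays open too: 0.6% of the 500 probe sets nearest in brightness fell as much, but this probe set was singled out for its fall, which voids the bound set beforehand, and which NFX1 form each probe set reads was not tested.

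HMGA2 and DICER1, textbook let-7 targets, led or stood high among the rises, and a candidate explanation is less repression by microRNAs in the cells with the NFX1-91 hairpin. Target lists of 5 microRNA families, written without genes already seen, had 29 higher and 14 lower of 82 genes. Their median of 0.15 lay at the 100th percentile of 10000 random lists matched on brightness (camera adjusted p = 0.0125, adjusted p = 0.122 with an estimated correlation). A drift of the arrays with genomic gene length could give such a percentile. Matching the random lists on that length too would then remove it, and it was still 99.97. Transcript length was not matched, so a drift that follows it stays open. The random lists also take genes as independent. Matched on brightness, the let-7 list by itself lay at percentile 80.4, with 9 higher and 4 lower members. By that matching miR-21 lay at 85.0, miR-200 at 94.0, miR-29 at 99.3 and miR-17 at 99.9. Matched on length too, the percentiles were 65.0 for let-7, 85.8 for miR-21, 91.7 for miR-200, 98.7 for miR-29 and 99.9 for miR-17. The high percentile predicted for let-7 was thus not met. Since its members went both ways, that alone does not exclude let-7. Both groups carried a hairpin, so a competing load could act only by differing between the hairpins. Such a difference and an effect of NFX1-91 were not tested apart.

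Fold change rose with genomic gene length (Spearman rho 0.13 across 11955 genes, which are not independent replicates), and of 5 equal classes of length the shortest had a median log2 fold change of -0.04, and the longest one of 0.04. From the shortest to the longest class, 23.5%, 39.2%, 50.4%, 52.5% and 59.1% of the called genes were higher. Drift from array to array is argued against: the slope between groups was 0.0758 per 10-fold length and single arrays around their group mean ranged over 0.0107. Brightness as the whole cause is argued against by a mean rho of 0.148 within 10 bins of brightness, above 0 in 9 of them. It was lowest in a dim bin (-0.00276) and highest in a brighter one (0.273). The bins share the same arrays and rho varied with brightness, so the SE of 0.0323 over bins is no test. A part of brightness in the dim bins stays open. Labelling or hybridisation done group by group cannot be told apart from the hairpin at that slope of 0.0758, because the labels give no batch, and a biological difference between the cells stays untested.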

How the results depend on the processing

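The alternative without an offset was chosen after the data were seen; the other alternatives were planned. The NFX1 change stayed below 0 and short of the threshold under each alternative run, from -0.27 to -0.08. Counts of higher and lower genes stayed within 1.5 times of 1760 and 2130 except by stricter thresholds: 364 and 690 at 1.5-fold or more, and 1136 higher at an adjusted p under 0.01 (1539 lower). Leaving out 1 array gave 1264 to 1846 higher and 1649 to 2081 lower genes, quantile normalization 1945 and 2004, and array weights 2419 and 2670. With an estimated correlation 0 lists were higher and 0 lower, against 1 and 2, in a setting whose few degrees of freedom let hardly any list pass. On ranks the p53 list missed the threshold and the hypoxia list passed it. With shared probe sets left out HLA-E (0.0275), THBS1 (-0.26), DNAJA1 (-0.25) and UQCRB (0.0742) changed sign; another probe set then stands for the gene, and the cause was not tested. Leaving out shared probe sets could replace the probe set of 12 of the 111 named genes called, of which 5 kept call and direction and 3 lost the call; 55 others have shared probe sets only, which leaves them untested. By the mean, 37 of the 43 with several probe sets kept both. In the other settings 104 to 111 of the 111 kept both. The replicate number as a block gave 1628 higher and 1970 lower genes. Arrays of the same number did not deviate together (residual correlations -0.058, 0.087 and -0.088), so the numbers pair nothing. The robust prior was not run for lists, since camera has no such option. Signal over background limits dim genes: 24.1% to 25.9% of probe sets lay below the offset.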

Other observations

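The lists in this part were written after the largest changes had been seen, without the genes already seen, so all tests here were chosen after a result was seen.

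Integrins, the receptors for extracellular matrix, had 7 higher and 1 lower of 11 measured members, among them ITGB5 (0.56), ITGA3 (0.45) and ITGB4 (0.34), while ITGAE fell by 0.47. Their camera adjusted p was 0.0554, and the adjusted p = 0.220 with an estimated correlation. Amino acid transporters had 3 higher and 5 lower of 15 (adjusted p = 0.262), SLC3A2 falling by 0.94 and SLC1A5 by 0.997, and SLC7A7 rising by 0.45. Aminoacyl-tRNA synthetases had 6 higher and 4 lower of 16 (adjusted p = 0.420), AARS1 falling by 0.78 and RARS1 rising by 0.44. DNA repair genes had 2 higher and 6 lower of 19 (adjusted p = 0.262), with BRCA1 lower by a log2 fold change of -1.07 and APEX1 by -0.43.

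Among the microRNA target lists, miR-29 targets had 6 higher and 0 lower of 14 (adjusted p = 0.00919, adjusted p = 0.122 with an estimated correlation), including TDG (1.08) and LAMC1 (0.56). miR-17 family targets had 7 higher and 5 lower of 18; their median lay at percentile 99.9 of lists matched on brightness, but camera, which weighs all members, did not call them (adjusted p = 0.262). Higher and lower members were 6 and 4 of 17 for miR-200 family targets (adjusted p = 0.262), 2 and 2 of 9 for miR-21 targets (0.678), and 9 and 4 of 27 for let-7 targets (0.156).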
